A study of Sus scrofa with 75 samples.

How the data were processed

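Short-read levels came from 40 Illumina libraries of heart, kidney, liver, lung and spleen from 8 animals, 4 coded BS and 4 coded DSE, and long-read levels from 10 PacBio libraries, 1 per pig group and tissue. Per the labels, RNA extraction used Trizol and then acid phenol, and ribosomal RNA was depleted for the Illumina libraries only. The gene and transcript tables were deposited as TPM, and their columns summed to 1000000. STAR 2.7.10a, Salmon 1.10.1 and the genome build susScr11 are named per the submitters' processing notes, which do not say which step made which table. The long-read table was deposited as counts of full-length reads per assembled transcript, with no normalization seen in the values, and nothing beyond PacBio IsoSeq is stated about how it was made. The annotation was written with rtracklayer 1.58.0, per the file headers. Another 20 columns of gene TPM, 20 of transcript TPM and 5 of full-length counts carried a code that matches no label and were not used, and the samples labelled DT were not analysed here. The short-read depth is unknown, which leaves the precision of single low TPM values unknown, and the full-length reads per library ranged from 119623 to 456783.

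Identifiers were used as the annotation gives them. Symbols came from the annotation for 17602 gene identifiers. The transcript table listed 155 names that differ from the annotation, and they were matched by their transcript identifier, after which all 94894 transcripts were found. Full-length reads were summed per gene through the transcript's own gene (51.9% of reads). Transcripts missing from the annotation were assigned through the other transcripts of the same long-read locus where these named 1 gene (35.9%). The reads of loci with several genes (3.16%) or with no annotated transcript (9.10%) were left out, which kept 87.7% of reads on 7929 genes. Whether the authors' counting used strand is not stated, so the reads of overlapping genes, antisense pairs and joint identifiers cannot be told apart. Overlaps were looked up only for the genes and transcripts named by the rule described below, and some of them are given beside the gene. A gene without such a remark can still overlap another.

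Tissues and pig groups were compared with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment at 0.05, among genes with a mean of at least 1 TPM in 1 or more of the compared groups. A gene was tissue-enriched where all 4 contrasts with the other tissues were at least 4-fold and the largest of their p-values passed, and depleted on the mirror rule. BS was compared with DSE within each tissue, and over tissues on each animal's mean, with at least 2-fold required. An interaction F test asked whether the difference varied between tissues. Signed differences are BS minus DSE. Transcript usage was tested on the log2 ratio of a transcript to the other transcripts of its gene with a pseudocount of 0.5 TPM. It covered genes with 2 or more transcripts and a mean of at least 5 TPM in every group and transcripts with a mean usage of at least 5%. Calls needed a shift of at least 20 points of percent. Full-length counts were tested with the quasi-likelihood test of edgeR 4.0.16 with TMM scaling, with pig group as a term, and DESeq2 1.42.0 was an alternative. Tables were read with the data.table package (1.17.8). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the inputs and drew the plots.

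A set of 30 gene lists with 443 genes, for cell types of these organs and for functional groups, was tested with camera at a preset correlation of 0.01 where at least 5 members were measured, which gave 149 tests, and with one-sided Fisher exact tests among tissue-enriched genes against tested genes with a symbol. Members counted as higher or lower passed an adjusted p of 0.05 with no minimum fold, over all genes or adjusted over the list alone. The lists, tests, thresholds, other settings and the rule for naming genes were chosen before the data were examined. The rule named, per tissue, the 5 genes with the largest fold over the next tissue at a mean of at least 10 TPM, the 2 with the largest fall at a mean of at least 10 TPM in every other tissue, and the first 4 measured members of the tissue's list. For the pig groups it named the 5 higher and 5 lower genes over tissues and 4 genes within each tissue at a mean of at least 5 TPM, all without overlap between the animals, and up to 4 passing members of each called list. For transcripts it named 6 genes by tissue and 3 by pig group. Genes of the mitochondrial genome, histones, immune receptor segments and LOC symbols were not named by fold, and some genes that the rule named are not reported here. Members of lists called within a tissue were instead named as the passing members with the lowest adjusted p, a choice made after their values were seen. The design had been written for 3 pig groups, and with 2 of them the F test became a single contrast. A planned comparison of genes with and without a reference gene was made on transcripts, since every gene carried a reference identifier.

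Libraries with the same code in different tissues were taken as 1 animal, as their titles read. Their deviations from the group means correlated by 0.122 on average over 80 pairs, of which 47 lay above 0.1 and the lowest at -0.110, against -0.0407 for other animals of the same group (permutation p = 1e-04, the smallest that 10000 resamples can give). Each tool was tested on simulated data with known changes. Of 100 genes changed between pig groups in lung, 80 were recovered at log2 1.5 and 99 at log2 3, with 5 unchanged genes called among 14812. Over tissues 98 of 100 were recovered at log2 1.5, of the tissue-enriched genes 99 of 100 at log2 3, and for the interaction 187 of 200 at log2 2. For transcript usage 193 of 200 by tissue and 194 of 200 by pig group were recovered at log2 2.5, and edgeR and DESeq2 each recovered 200 of 200 at log2 4. In the list simulation the 1 raised list was recovered and 1 unchanged list was called.

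Alternatives covered a pseudocount of 0.1 TPM, no filter on low values, median-ratio scaling of the TPM columns, the animal or its number as a block, each animal left out in turn, other minimum folds, camera with an estimated correlation, fry, stricter limits on transcripts and full-length reads, and other settings for the full-length counts. After seeing the data, TPM rescaled without mitochondrial and ribosomal RNA genes, and the subtraction of a smoothed trend on transcript length and on the number of annotated genes within 500 kb (span 0.3), were added. Other divisions of the animals into groups of the same sizes were refitted for each comparison. No genome sequence was used here, so GC content was not examined.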

Results

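RNA from heart, kidney, liver, lung and spleen was measured in adult male pigs aged 12 months. The pigs analysed here fell into 2 groups whose titles carry the codes BS and DSE. Samples of a further group, coded DT, were not analysed, and the labels do not say what the codes stand for. For BS and DSE, Illumina RNA sequencing after depletion of ribosomal RNA gave 40 libraries, 1 for each of the 5 tissues of 4 BS and 4 DSE animals. PacBio IsoSeq, which reads whole transcripts, gave 10 libraries of these groups, 1 for each pig group and tissue and therefore without replicates inside a pig group. The series title presents the work as a transcriptome of local pigs from China. Short-read levels were deposited as TPM, the relative level of each transcript in its library, for 35798 genes and 94894 transcripts, with every library summing to 1000000, so the depth of these libraries is unknown. Long-read levels were deposited as counts of full-length reads per transcript. The BS libraries held 368976 full-length reads in heart, 456783 in kidney, 282770 in liver, 204718 in lung and 119623 in spleen. The DSE libraries held 224308, 168139, 216155, 208658 and 144216 in the same order of tissues. Intervals given for shares of genes cover counting error only.

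The assembled annotation extended the reference mainly at genes already known. It held 35936 genes and 95050 transcripts on build susScr11, of which 34778 transcripts (36.6%) came from the long reads and lay on 8038 genes (22.4%). Of these long-read transcripts 2477 had no full-length read in the BS and DSE libraries used here. LMO7, which codes for a protein of cell junctions and the cytoskeleton (ENSSSCG00000040184, chromosome 11, 47911045 to 48133448), had 110 long-read transcripts, the most of any gene. MBNL1, a splicing regulator, followed with 98, EIF4A2, a translation initiation helicase, with 83, RBM39, another splicing factor, with 80, and SORBS2, an adaptor protein of the muscle Z-disc, with 79. Long-read transcripts had a median of 11 exons and 3229 nt, against 6 exons and 2924 nt for Ensembl transcripts, and 0 of them had a single exon against 18.3% of the Ensembl ones. A mean of at least 0.1 TPM in 1 or more tissues was reached by 91.6% of long-read and 56.7% of Ensembl transcripts. Long-read transcripts were found by sequencing these same organs, so their higher share follows at least in part from how they were found. Every gene of the annotation carried a reference identifier, some of them joint identifiers, so genes outside the reference could not be examined. Ensembl transcripts lay on 35633 of the 35936 genes, and entries with long-read transcripts alone were not examined separately.

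The number of expressed genes differed between tissues, and lung expressed the most. At least 1 TPM was reached by 14346 ± 370 genes in lung (SD, n = 8), 13418 ± 211 in spleen, 13284 ± 171 in kidney, 11846 ± 184 in heart and 11585 ± 235 in liver. The F statistic over tissues was 178, with p = 1e-05 by a permutation test of tissue labels within animals, the smallest that 100000 resamples can give. Transcripts of the mitochondrial genome took 38.2 ± 4.34% of heart TPM (SD, n = 8), 22.6 ± 2.53% in kidney, 9.42 ± 1.43% in liver, 7.49 ± 0.720% in lung and 6.87 ± 1.68% in spleen. Long-read transcripts took 29.8 ± 1.18% of all TPM in heart and 43.9 ± 1.45% in liver, the lowest and highest means of the 5 tissues. These totals include the mitochondrial genome, so the shares do not rank the tissues by their other transcripts.

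**Figure D1:**
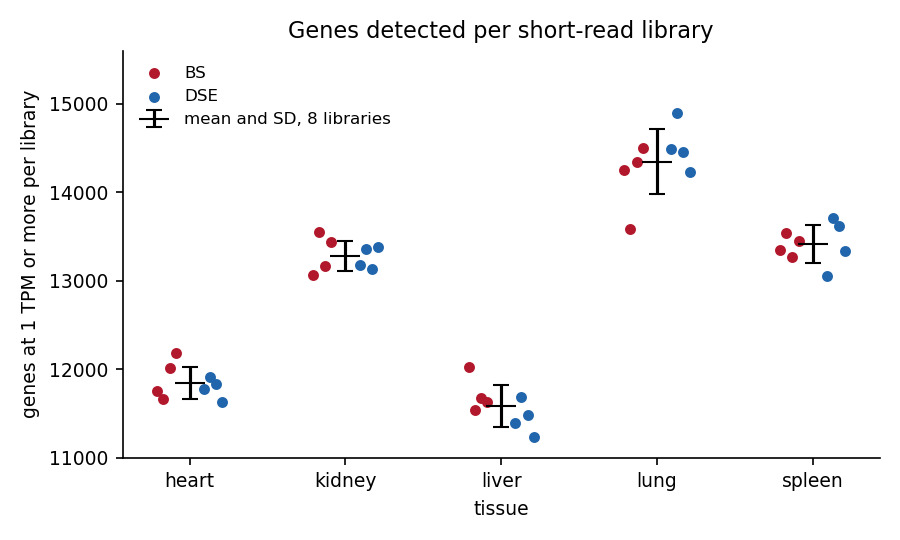
Each point is 1 short-read library and shows the number of genes with at least 1 TPM (vertical axis, which does not start at 0) by tissue, with BS and DSE animals in different colours and the mean and SD of 8 libraries beside them. Lung averaged 14346 genes and liver 11585.

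The comparison of tissues asked which genes mark each organ. Ranked by fold over the next tissue, with genes of the mitochondrial genome not named, heart was led by genes of the contractile apparatus. MYL2, the ventricular regulatory light chain of myosin (ENSSSCG00000039710, chromosome 14, 32205273 to 32213722), averaged 11260 ± 1224 TPM in heart (SD, n = 8) and was higher there than in liver, the next tissue, by log2 12.64 (limma adjusted p = 3.2e-24). Its liver mean of 5.996 ± 16.6 TPM came mostly from the BS4 library with 47.1 TPM, while no other library outside the heart passed 0.841 TPM. Without BS4 the folds were log2 13.33 for MYL2 and 13.13 for TNNT2. The cardiac troponins TNNT2 (10930 ± 2112 TPM) and TNNC1 (14180 ± 1425 TPM), the skeletal actin ACTA1 (12500 ± 3802 TPM) and the slow myosin MYH7 (5480 ± 585 TPM) were each higher in heart by log2 11.67 or more. Of the 16 measured members of the heart muscle list, 15 were heart-enriched (one-sided Fisher exact adjusted p = 5.65e-24), including MYL3 (5232 ± 1244 TPM) and the fast myosin MYH6 (84.5 ± 62.0 TPM). The skeletal muscle list had 3 of 5 measured members enriched in heart, ACTA1, CKM and MYOT (adjusted p = 0.000778). The adipocyte list had 3 of 8, the lipid-handling genes PLIN4, LPL (311 ± 64.0 TPM) and FABP4 (157 ± 95.8 TPM; adjusted p = 0.00329), while the adipocyte hormone ADIPOQ averaged 0.898 ± 1.09 TPM in heart. NHERF1, a scaffold of epithelial transporters, was lowest in heart at 2.29 ± 0.595 TPM, by log2 -4.78 against spleen, and complement C4A was lower there by log2 -3.71 against lung.

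In kidney the largest folds over the next tissue belonged to transporters and proteins of the tubule. UMOD, the main protein of normal urine (ENSSSCG00000007859, chromosome 3, 25473158 to 25492278), averaged 4166 ± 1824 TPM in kidney (SD, n = 8) and was higher there than in spleen, the next tissue, by log2 11.57 (limma adjusted p = 2.8e-36). The organic anion transporter SLC22A8 (935 ± 205 TPM), the phosphate transporter SLC34A1 (890 ± 319 TPM), the proximal tubule gene TMIGD1 (654 ± 318 TPM) and the lactate transporter SLC5A12 (513 ± 309 TPM) followed, each by log2 8.63 or more. The kidney epithelium list had 16 of its 17 measured members enriched (adjusted p = 2.11e-23), among them the salt transporters SLC12A1 (276 ± 77.2 TPM) and SLC12A3 (189 ± 22.9 TPM) and the water channel AQP2 (296 ± 172 TPM). The exception was AQP3, at 102 ± 52.0 TPM in kidney and 398 ± 194 TPM in spleen, a gene named after its values were seen. Angiotensinogen, AGT, was lower in kidney than in every other tissue, at 2.003 ± 1.663 TPM and by log2 -3.79 against spleen, as was the complement regulator C4BPA, by log2 -3.58 against heart.

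Plasma proteins had the largest folds over the next tissue in liver. ALB, serum albumin (ENSSSCG00000008948, chromosome 8, 69531487 to 69721696, a locus annotated across AFP and AFM), averaged 57790 ± 15380 TPM in liver (SD, n = 8) and was higher there than in heart, the next tissue, by log2 13.36 (limma adjusted p = 5.96e-22). The plasma proteins APOH (4970 ± 1176 TPM), AHSG (3340 ± 718 TPM), SERPINA1 (2048 ± 481 TPM) and PLG (2006 ± 158 TPM) were each higher in liver by log2 9.79 or more. Of 19 measured members of the hepatocyte list 18 were liver-enriched (adjusted p = 1.27e-28), with the apolipoproteins APOA1 at 5373 ± 907 TPM, APOA2 at 645 ± 195 TPM and APOB at 1247 ± 192 TPM. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was the member that did not pass, at 103 ± 132 TPM in liver and 114 ± 46.1 TPM in lung, and it was named after its values were seen. The acute phase list had 6 of 7 members enriched in liver (adjusted p = 6.08e-09), with CRP at 672 ± 542 TPM, ITIH4 at 3276 ± 1808 TPM and LBP at 484 ± 207 TPM, and without LCN2, at 6.38 ± 4.91 TPM in liver and 183 ± 64.0 TPM in lung. The drug and bile acid metabolism list had 6 of 12 (adjusted p = 6.49e-07), including CYP1A1 (48.4 ± 32.9 TPM), CYP1A2 (75.4 ± 34.7 TPM) and CYP2C49 (765 ± 319 TPM). Fatty acid synthesis had 4 of 15 in liver, namely ELOVL6, THRSP, DGAT2 and FADS2 (adjusted p = 0.00175), and cholesterol synthesis 4 of 17, among them IDI1, DHCR7 and MSMO1 (adjusted p = 0.00274). The lipogenic enzymes FASN and SCD were instead highest in lung, with FASN at 79.7 ± 41.1 TPM there and 17.2 ± 15.2 TPM in liver and SCD at 120 ± 27.1 and 21.8 ± 15.5 TPM. CLIC5, a chloride channel protein, and PKIA, a protein kinase inhibitor, were lowest in liver, by log2 -4.50 and -3.67 against the next tissue.

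Surfactant genes led lung by fold over the next tissue. SFTPC, surfactant protein C of alveolar type II cells (ENSSSCG00000009619, chromosome 14, 6440309 to 6443095), averaged 25050 ± 13210 TPM in lung (SD, n = 8) and was higher there than in liver, the next tissue, by log2 13.90 (limma adjusted p = 2.9e-34). SFTPA1 (4652 ± 1905 TPM), CBR2 (3431 ± 755 TPM), SFTPB (1710 ± 659 TPM) and AGER, a receptor of alveolar type I cells (1400 ± 281 TPM), were each higher in lung by log2 9.79 or more. All 14 measured members of the lung epithelium list were enriched (adjusted p = 2.65e-21), with SFTPD at 231 ± 152 TPM, at a locus that overlaps MBL1. The immediate early list, made of genes that respond within minutes to stimulation or handling, had 12 of 18 members enriched in lung (adjusted p = 4.28e-14). FOS averaged 658 ± 319 TPM in lung against 110 ± 25.7 TPM in spleen, JUN 505 ± 182 TPM against 108 ± 19.8 TPM in heart, and FOSB 63.4 ± 23.7 TPM against 3.73 ± 2.39 TPM in spleen. Genes at least 4-fold lower in lung than in every other tissue were 2, the cell adhesion gene CDH2 (0.964 ± 0.180 TPM, log2 -3.76) and the sterol hydroxylase CYP27A1 (1.81 ± 1.16 TPM, log2 -2.52).

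The genes with the largest fold in spleen included SPIC and TLX1. SPIC, a transcription factor of red pulp macrophages (ENSSSCG00000000867, chromosome 5, 82726337 to 82795864), averaged 736 ± 254 TPM in spleen (SD, n = 8) and was higher there than in kidney, the next tissue, by log2 8.34 (limma adjusted p = 2.48e-31). The integrin ITGAD (351 ± 137 TPM), the receptor GPR82 (523 ± 144 TPM, inside the CASK gene on the other strand), the adhesion molecule VCAM1 (2045 ± 723 TPM) and TLX1, which the spleen needs to form (54.3 ± 15.3 TPM), were each higher by log2 5.20 or more. Of 13 measured B cell genes 10 were spleen-enriched (adjusted p = 7.54e-17), with MS4A1 at 119 ± 39.7 TPM, CD79A at 205 ± 69.6 TPM and CD79B at 85.3 ± 39.4 TPM. The T and NK cell list had 5 of 14, namely CD3D, CD3E, LCK, CD247 and KLRK1 (adjusted p = 3.23e-06), and the spleen stroma list 4 of 8, namely TLX1, NKX2-3, SPIC and LTB (adjusted p = 1.07e-05). The stroma list members LYVE1 and PDPN were highest in lung, with LYVE1 at 191 ± 73.2 TPM and PDPN at 151 ± 31.0 TPM. The flavin monooxygenase FMO1 was lowest in spleen at 0.178 ± 0.0869 TPM, by log2 -5.95 against heart, at a locus that a joint gene identifier also covers, and the desmosome gene PERP by log2 -4.13.

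In all, 288 genes were enriched in heart, 422 in kidney, 362 in liver, 435 in lung and 244 in spleen out of 16905 tested, each at least 4-fold above every other tissue. Genes at least 4-fold below every other tissue numbered 120, 12, 123, 2 and 24 in the same order. Across 30 lists and 5 tissues, 14 of 150 Fisher exact tests passed, all of them described with their tissue. The lists of neutrophil, macrophage and endothelial genes passed in no tissue, with adjusted p = 0.0927 for neutrophils in lung, 0.0641 for macrophages in spleen and 0.207 for endothelium in lung. With median-ratio scaling of the libraries in place of TPM as deposited, heart had 501 enriched and 61 depleted genes, liver 554 and 25, and lung 224 and 7, while kidney had 24 depleted genes. The tissue genes named by the rule set in advance kept their direction and stayed past the threshold under every alternative run. The other genes named above were not run under them.

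Where full-length reads were enough, long reads placed most short-read enriched genes in the same organs. ACTA1 had 5169 full-length reads in BS heart and 3466 in DSE heart and was higher in heart than in spleen, the next tissue, by log2 12.11 (edgeR adjusted p = 3.57e-45). PLN, the regulator of the cardiac calcium pump, had 5755 and 4772 reads in heart. UMOD had 2925 and 2275 in kidney and GPX3, the plasma glutathione peroxidase, 5484 and 4378. ALB had 31615 and 40386 reads in liver, SLC34A2, a phosphate transporter of alveolar type II cells, 1744 and 1316 in lung, and VCAM1 1541 and 3000 in spleen. Enriched genes numbered 174 in heart, 124 in kidney, 187 in liver, 61 in lung and 58 in spleen out of 4110 tested, with 1 BS and 1 DSE library per tissue as the replicates. Of the short-read enriched genes that the long-read test covered, 96 of 101 in heart, 106 of 131 in kidney, 120 of 121 in liver, 54 of 82 in lung and 34 of 45 in spleen were called by both methods. Among 724 short-read enriched genes with at least 5 full-length reads, 715 had their highest long-read share in the same tissue, 98.8% (exact 95% interval 97.7 to 99.4, over genes, which are not independent). DESeq2 called 52 genes in kidney, 108 in liver and 15 in lung. Without the pig group as a term edgeR called 22 in lung and 13 in spleen.

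Summed over the 5 tissues, transcripts known from long reads were tissue-enriched more often than Ensembl transcripts. This did not hold in lung or spleen. Of 24968 long-read transcripts tested 2379 were enriched in 1 tissue, 9.53%, against 1869 of 22429 Ensembl transcripts, 8.33%. The odds ratio was 1.16 (95% interval 1.09 to 1.24, Fisher exact p = 5.56e-06). Within 5 strata of expression level the odds ratio was 1.42 (Mantel-Haenszel 95% interval 1.33 to 1.52). Heart had 989 enriched transcripts, 610 of them from long reads, and 337 belonged to genes that were not themselves heart-enriched. Of the enriched transcripts 300 of 701 in lung and 218 of 463 in spleen came from long reads, less than the long-read share of the transcripts tested. Long-read transcripts were found in these same tissues at unequal depth. Whether this shaped the odds ratios and the shares by tissue was not tested.

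The choice of transcript within a gene also differed between organs. SLC25A3, the mitochondrial phosphate carrier, used the long-read transcript PB.7437.1 (ENSSSCG00000000886, chromosome 5, 85284315 to 85292305, 8 exons) for 92.7 ± 1.73% of its TPM in heart (SD, n = 8) and for 0.00663 ± 0.0124% in kidney, where PB.7437.2 took 92.9 ± 1.53% (limma adjusted p = 2.95e-23). CYP2E1, an ethanol-oxidising enzyme of the liver, used the transcript ENSSSCT00000011795 for 92.3 ± 1.78% in liver, while the longer ENSSSCT00000088500, which runs into the SYCE1 locus, took 99.8 ± 0.324% in lung, where the gene averaged 6.12 ± 1.01 TPM. STAT2, which carries interferon signals, used ENSSSCT00000000428 for 96.6 ± 0.628% in liver, and that transcript was listed at 0 in every lung library (the locus overlaps IL23A). The small heat shock protein CRYAB used ENSSSCT00000056695 for 94.9 ± 1.67% in heart, where PB.12089.8, which starts further out, took 4.41 ± 1.26% against 96.4 ± 2.54% in lung. COX6A2, a muscle subunit of cytochrome oxidase, used ENSSSCT00000059824 for 94.7 ± 1.24% in heart, and FPGS, which retains folates in cells and overlaps ENG, used ENSSSCT00000006186 for 99.7 ± 0.368% in spleen and 7.14 ± 3.15% in liver. In all, 1105 of 4993 genes tested (22.1%) had a transcript whose usage passed and shifted by at least 20 points of percent between tissues, and in 659 the leading transcript differed. The gene's largest shift set heart highest in 397 of the 1105 called genes and lung in 84. Genes with a mean of at least 20 TPM in every tissue gave 250 calls, from fewer genes tested, and a shift of at least 40 points gave 303.

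**Figure D2:**
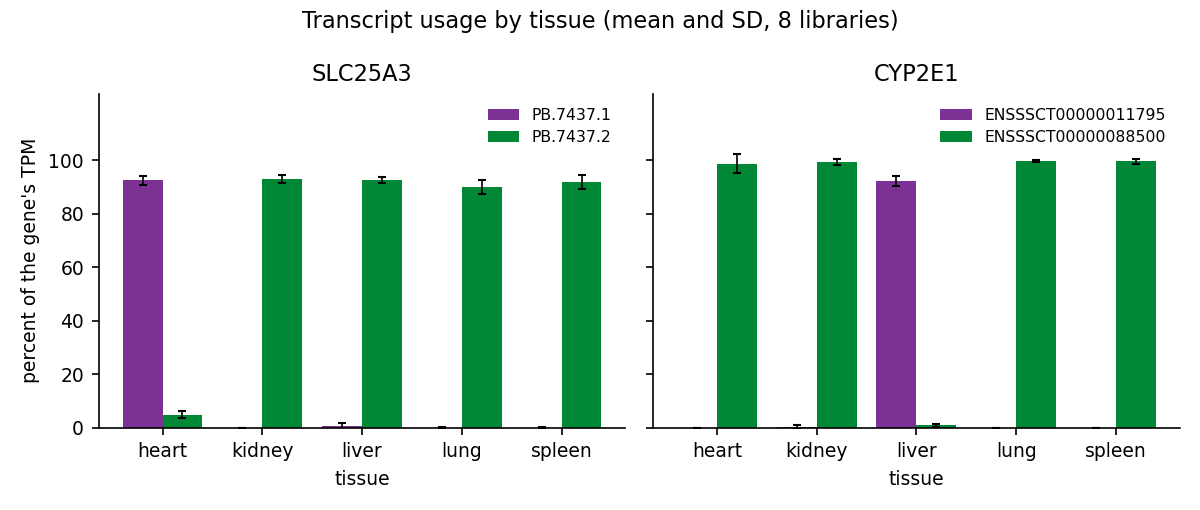
Bars show the mean usage of a transcript by tissue, as a percentage of the TPM of its gene, with SD over 8 short-read libraries. The transcripts are the main pair of SLC25A3 and of CYP2E1. PB.7437.1 took 92.7% of SLC25A3 in heart, and ENSSSCT00000011795 took 92.3% of CYP2E1 in liver.

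The comparison of BS with DSE asked how the pig groups differ across organs, with each animal counted once as its mean over 5 tissues. CCDC152 (ENSSSCG00000016867, chromosome 16, 27471003 to 27538665), which shares its locus with the selenium carrier gene SELENOP of the RefSeq annotation, averaged 391 ± 27.3 TPM in BS and 1300 ± 48.6 TPM in DSE (SD, n = 4 each), a log2 difference of -1.61 (limma adjusted p = 3e-06). CETN3, a centrosome protein, was lower in BS at 31.2 ± 3.46 against 94.9 ± 12.4 TPM, and SLC40A1, the iron exporter ferroportin, at 173 ± 72.0 against 354 ± 28.0 TPM (log2 -1.30, adjusted p = 1.5e-05). RAB1B, a trafficking GTPase, averaged 23.8 ± 10.6 against 74.3 ± 3.21 TPM and PET117, an assembly factor of cytochrome oxidase, 1.78 ± 1.06 against 8.04 ± 1.65 TPM, though a joint identifier covers RAB1B and KAT14 covers PET117. Higher in BS were the membrane protein gene TMEM238 (43.0 ± 8.29 against 8.04 ± 1.48 TPM, log2 2.12, adjusted p = 7.03e-06) and PPP1R14A, an inhibitor of myosin phosphatase (46.1 ± 9.54 against 15.3 ± 2.96 TPM, log2 1.69). HBM, an alpha-like globin next to NPRL3, averaged 162 ± 147 against 10.03 ± 6.27 TPM (log2 2.53, and 3.16 without BS3), and NCBP2AS2, which lies opposite NCBP2, 15.4 ± 6.02 against 2.73 ± 1.99 TPM. The sialyltransferase ST3GAL1, whose reads a joint identifier shares, averaged 4.38 ± 2.80 TPM in BS and was listed at 0 in DSE.

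Over tissues 234 of 16905 genes differed at least 2-fold, with 172 higher in BS and 62 higher in DSE. The 4 BS and 4 DSE animals did not overlap for 210 of them, and chance separates 2.86% of genes in this way, while 8444 of all 16905 genes were separated. With no minimum fold 9342 genes passed the adjusted p. The pig group difference correlated between tissues across 10433 genes by r = 0.715 to 0.817 (genes are not independent replicates, and the tissues came from the same 8 animals, so a value above 0 can arise without a pig group difference). In 31 genes BS was higher by at least 2-fold and past the adjusted p in every one of the 5 tissues, including the MHC class II invariant chain CD74, the lipolysis inhibitor G0S2, the NAD synthesis enzyme NAPRT, TMEM238 and PPP1R14A. By the same rule DSE was higher in all 5 in 4 genes, CETN3, CCDC152 and a pair without a symbol. Of these names CD74, G0S2 and NAPRT were chosen after their values were seen. Median-ratio scaling gave 286 genes with 248 (86.7%) higher in BS, against 73.5% as deposited, and 63.3% of 256 were higher in BS after TPM were rescaled without mitochondrial and ribosomal RNA genes.

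Within organs the pig groups differed at 318 genes in heart, 619 in kidney, 409 in liver, 1360 in lung and 414 in spleen. In heart SNAP91, a clathrin adaptor (ENSSSCG00000004453, chromosome 1, 82541018 to 82698644), averaged 0.444 ± 0.225 TPM in BS and 6.49 ± 2.49 TPM in DSE (SD, n = 4 each), by log2 -2.33 (limma adjusted p = 0.000329). In kidney APOB, the carrier protein of lipoproteins, averaged 0.281 ± 0.272 against 10.02 ± 5.68 TPM (log2 -3.01, adjusted p = 0.0014) and the receptor gene ADGRG7 0.923 ± 1.502 against 8.38 ± 5.73 TPM, while TMEM238 was higher in BS by log2 2.39 and CCDC152 lower by log2 -2.61. In liver the bile acid exporter subunit SLC51B, which overlaps RASL12, averaged 17.5 ± 6.32 against 2.08 ± 1.24 TPM (log2 2.61, adjusted p = 0.00269). The natriuretic peptide receptor NPR2, which overlaps SPAG8, averaged 19.1 ± 4.21 against 3.13 ± 1.82 TPM in liver, the nucleotide transporter SLC17A9 33.0 ± 7.43 against 6.51 ± 3.31 TPM and the p53 target PHLDA3 26.2 ± 8.54 against 4.99 ± 2.21 TPM. In lung the secretory cell gene AGR2 averaged 1.45 ± 1.52 against 89.2 ± 143 TPM (log2 -3.96, adjusted p = 0.0134), where DSE2 alone held 303 TPM, and the inducible chaperone HSPA6, at a jointly identified locus, 103 ± 125 against 4.59 ± 1.52 TPM. In spleen the antimicrobial peptide gene PG-2 averaged 47.9 ± 46.5 against 2.31 ± 1.48 TPM, lactotransferrin LTF 21.0 ± 22.5 against 0.541 ± 0.118 TPM and PGLYRP1 18.4 ± 16.6 against 0.811 ± 0.652 TPM. NCBP2AS2 was higher in BS and listed at 0 in DSE in heart and lung, averaged 15.01 ± 6.736 against 1.31 ± 2.63 TPM in spleen, and PET117 was listed at 0 in BS in heart and lung. Some folds moved over 1.5 times without 1 animal. HSPA6 differed by log2 2.62 without BS3 and 4.18 without BS2, AGR2 by log2 -2.91 without DSE2 and LTF by log2 2.60 without BS1. PG-2 differed by log2 2.88 without BS4, and NCBP2AS2 in spleen by log2 3.86 without DSE1.

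BS was the higher group in 267 of the 318 genes in heart, 427 of 619 in kidney, 331 of 409 in liver, 404 of 1360 in lung and 197 of 414 in spleen. The median of all genes lay at log2 -0.21 in lung and -0.12 in spleen. The balance in lung and spleen depended on scaling, since median-ratio scaling gave 765 of 1080 genes (70.8%) higher in BS in lung, against 29.7% as deposited, and 281 of 392 (71.7%) in spleen, against 47.6%. Genes called under both scalings numbered 705 in lung and 302 in spleen, all with the same direction. In heart 56.2% of 333 genes were higher in BS after TPM were rescaled without mitochondrial and ribosomal RNA genes, against 84.0%. The mitochondrial share of heart TPM was 34.7 ± 0.964% in BS and 41.7 ± 3.24% in DSE (SD, n = 4 each, 2-sided exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.214 over 15 tests). The liver shares were 8.33 ± 1.26% and 10.5 ± 0.0273% with the same p. Without the animal BS3 kidney had 1059 genes, and without BS2 lung had 870. The pig group genes named by the rule set in advance kept their direction and call under every alternative run.

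**Figure D3:**
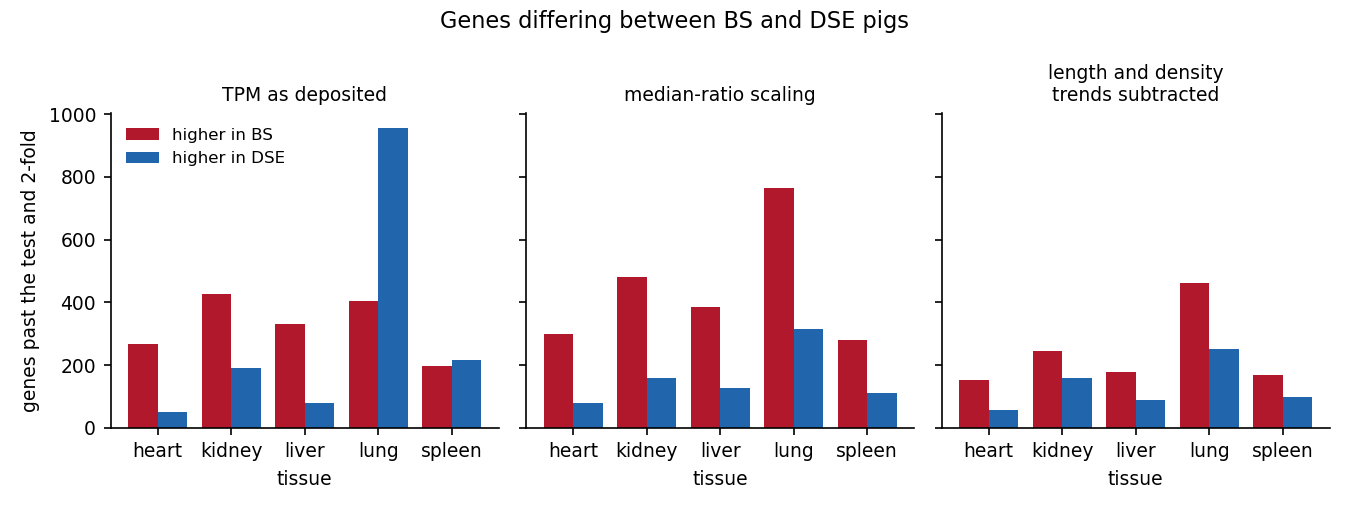
Side-by-side bars show, for each tissue, the number of genes at least 2-fold higher in BS and in DSE at a limma adjusted p under 0.05. The panels hold TPM as deposited, median-ratio scaling, and the trends on transcript length and gene density subtracted. In lung 404 genes were higher in BS and 956 in DSE as deposited, against 765 and 315 with median-ratio scaling.

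The signed BS minus DSE difference went with the number of neighbours of a gene and with the length of its transcripts. Among the genes with the fewest neighbours, 1 to 13 annotated genes within 500 kb, the median BS minus DSE difference was log2 -0.20 in heart, -0.30 in kidney, -0.20 in liver, -0.51 in lung and -0.34 in spleen. Among those with the most, 39 to 87, it was 0.42, 0.47, 0.43, 0.33 and 0.25 in the same order. Over tissues the difference correlated with the number of neighbours across 10433 genes by Spearman rho 0.505 and with transcript length by rho -0.307 (genes are not independent replicates). The size of the correlation with gene density was 0.438 to 0.501 in 16 pairs of 1 BS and 1 DSE animal and 0.0248 to 0.255 in 12 pairs of animals from 1 group. With both trends subtracted, a choice made after seeing the data, 209 genes passed in heart, 404 in kidney, 268 in liver, 715 in lung, 266 in spleen and 180 over tissues, of which 154, 256, 197, 468, 193 and 131 had also passed before.

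**Figure D4:**
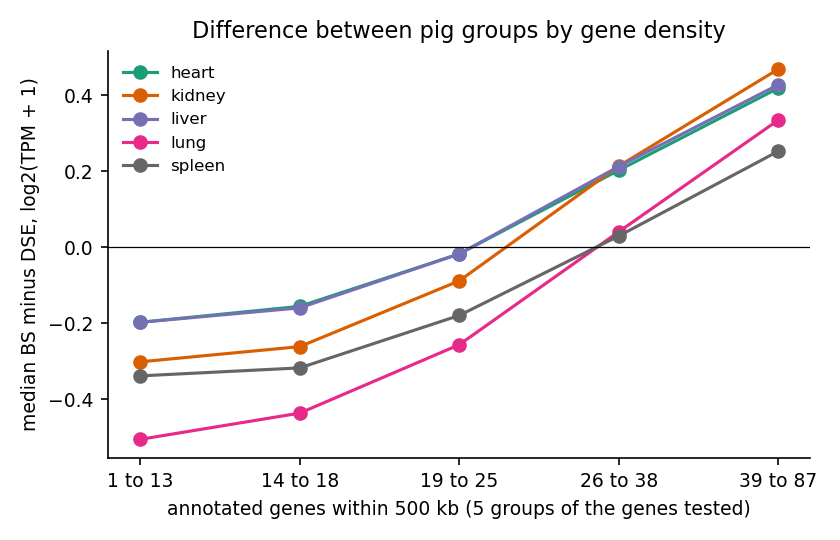
Each line is a tissue and shows the median BS minus DSE log2 difference (vertical axis) of genes in 5 groups by the number of annotated genes within 500 kb (horizontal axis). In lung the median went from -0.51 in the group with the fewest neighbours to 0.33 in the densest.

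Most measured genes of antigen presentation were higher in BS over tissues. List members were counted with no minimum fold, and by that rule 4252 of all 16905 genes tested were higher in BS over tissues. Within tissues 2863 of 12283 were higher in heart, 2650 of 13820 in kidney, 2130 of 12147 in liver, 2147 of 15025 in lung and 1496 of 13913 in spleen. CD74 averaged 354 ± 26.9 TPM over tissues in BS and 116 ± 18.6 TPM in DSE (SD, n = 4 each), by log2 1.63 (limma adjusted p = 1.7e-05), and the MHC class II activator CIITA 14.99 ± 2.698 against 9.77 ± 0.653 TPM. All 6 measured MHC class II genes were higher in BS over tissues, and all 6 adjusted over the list alone (camera adjusted p = 0.0172, and adjusted p = 0.919 with an estimated correlation). The peptide-loading gene TAPBP averaged 102 ± 2.45 against 61.6 ± 3.14 TPM and the peptide transporter TAP2 28.9 ± 0.826 against 20.4 ± 0.853 TPM. Of 7 MHC class I genes 6 were higher in BS over tissues, and 6 adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.919 with an estimated correlation), and B2M was not, at 6950 ± 785 against 7776 ± 642 TPM. Of 12 macrophage genes 6 were higher and 1 lower in BS over tissues, and as many adjusted over the list alone (camera adjusted p = 0.212, fry adjusted p = 0.0115). In liver 6 of 12 were higher (camera adjusted p = 0.0596). The class I list was also called in liver, with 6 of 7 higher and 6 adjusted over the list alone (adjusted p = 0.0136, and adjusted p = 0.919 with an estimated correlation), and in lung, with 3 of 7 and 3 (adjusted p = 0.0172, and adjusted p = 0.919 with an estimated correlation). The class II list was called in lung, with 2 of 6 higher and 5 adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.919 with an estimated correlation). In kidney 2 of its 6 members were higher, and 5 adjusted over the list alone (adjusted p = 0.0485, and adjusted p = 0.919 with an estimated correlation), a call lost with median-ratio scaling (adjusted p = 0.0675) and without BS1, BS4, DSE1, DSE2 or DSE3 (adjusted p = 0.051 to 0.11). With the length and density trends subtracted the class II calls were lost over tissues (adjusted p = 0.0662), in lung (0.0681) and in kidney (0.128), and the class I call in lung (0.0591).

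Some erythroid and cell cycle genes were higher in BS as well. In lung HBM averaged 129 ± 59.9 TPM in BS and 12.6 ± 6.25 TPM in DSE (SD, n = 4 each, log2 3.23, limma adjusted p = 0.00176) and the red cell membrane gene GYPC 88.7 ± 16.2 against 43.6 ± 12.4 TPM. Of 7 erythroid genes measured there 4 were higher in BS, and 6 adjusted over the list alone (camera adjusted p = 0.00416, and adjusted p = 0.919 with an estimated correlation). In spleen 1 of 9, HBM, was higher in BS, a share near that of all genes tested there (1496 of 13913), and 0 adjusted over the list alone. The list was called in spleen (camera adjusted p = 0.0136, and adjusted p = 0.919 with an estimated correlation), and the call was lost without BS1 (adjusted p = 0.0518) and with median-ratio scaling (adjusted p = 0.0675). Over tissues 5 of 10 erythroid genes were higher, and 4 adjusted over the list alone (adjusted p = 0.0485, and adjusted p = 0.919 with an estimated correlation), a call lost with median-ratio scaling (0.114), with the trends subtracted (0.0681) and without BS1, BS4, DSE1 or DSE4 (0.0537 to 0.0913). The cell cycle list had 6 of 16 members higher in BS in lung and 6 adjusted over the list alone (adjusted p = 0.00416, and adjusted p = 0.919 with an estimated correlation). The mitotic gene UBE2C averaged 43.3 ± 19.9 against 13.6 ± 1.48 TPM and PLK1 9.80 ± 3.38 against 3.52 ± 0.826 TPM. In spleen 3 of 16 were higher, UBE2C, AURKB and PLK1, and 3 adjusted over the list alone (adjusted p = 0.0133, and adjusted p = 0.919 with an estimated correlation), a call lost without BS4 or DSE3 (0.0512 to 0.0615). Over tissues 7 of 16 were higher in BS and 1, NUSAP1, in DSE, and as many adjusted over the list alone (adjusted p = 0.0393, and adjusted p = 0.919 with an estimated correlation), a call lost without BS1, BS4, DSE2 or DSE4 (0.0507 to 0.0777). In spleen 3 of 6 neutrophil genes were higher in BS, LTF, S100A8 (148 ± 151 against 16.2 ± 5.50 TPM) and S100A12 (184 ± 202 against 19.3 ± 10.4 TPM), and 4 adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.919 with an estimated correlation), a call lost with median-ratio scaling (0.0789).

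Some heat shock, immediate early and cholesterol synthesis genes differed in lung. The small heat shock protein HSPB1 averaged 1169 ± 244 TPM in BS lung and 333 ± 31.0 TPM in DSE lung (SD, n = 4 each, log2 1.79, limma adjusted p = 0.000829) and the chaperone partner DNAJB1 413 ± 168 against 99.4 ± 24.7 TPM. Of 14 heat shock genes 6 were higher in BS and 3 in DSE, and 8 and 3 adjusted over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.919 with an estimated correlation), with HSPA4L lower in BS at 4.59 ± 1.88 against 12.3 ± 3.97 TPM. The immediate early list had 6 of 18 members higher in BS and 1 in DSE, and as many adjusted over the list alone (adjusted p = 0.00416, and adjusted p = 0.919 with an estimated correlation). JUNB averaged 319 ± 17.2 against 123 ± 58.8 TPM and EGR3 5.62 ± 1.45 against 1.41 ± 0.390 TPM, while KLF4 was lower in BS at 138 ± 15.1 against 180 ± 14.8 TPM. Of 16 cholesterol synthesis genes 6 were higher in BS, and 6 adjusted over the list alone (adjusted p = 0.0136, and adjusted p = 0.919 with an estimated correlation). The mevalonate pathway enzyme MVD averaged 29.3 ± 5.43 against 11.5 ± 2.27 TPM and lanosterol synthase LSS 33.2 ± 4.36 against 17.1 ± 4.15 TPM.

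Some matrix, macrophage and mitochondrial genes differed in other organs. In heart the matrix genes COL6A1 (119 ± 22.4 TPM in BS against 57.8 ± 13.8 TPM in DSE, SD, n = 4 each, log2 1.04, limma adjusted p = 0.00279), COL4A2 (192 ± 40.8 against 98.0 ± 22.3 TPM) and BGN (46.7 ± 15.6 against 19.1 ± 4.90 TPM) were higher in BS. They belonged to 7 of 15 collagen and matrix genes higher in BS, with 8 adjusted over the list alone (camera adjusted p = 0.0485, and adjusted p = 0.919 with an estimated correlation), a call lost without BS3, BS4, DSE1, DSE3 or DSE4 (0.0598 to 0.107). With the length and density trends subtracted, a choice made after seeing the data, the heart call stayed (camera adjusted p = 0.000707). The list then also passed, higher in BS, in kidney (0.000707), liver (0.00738), lung (0.0303), spleen (0.0191) and over tissues (0.000732). Other lists gained calls by this subtraction too, including cholesterol synthesis in kidney, higher in BS (camera adjusted p = 0.00557). Lower in BS were mitochondrial genes in kidney (0.00557) and B cell genes in lung (0.0115). In kidney the macrophage receptor CSF1R (17.1 ± 5.04 against 5.03 ± 0.695 TPM) and the complement gene C1QC (67.6 ± 21.8 against 23.5 ± 3.02 TPM) were among 6 of 11 macrophage genes higher in BS, with 6 adjusted over the list alone (adjusted p = 0.0485, and adjusted p = 0.919 with an estimated correlation). That call was lost with median-ratio scaling (0.0541) and without BS1, BS4, DSE2, DSE3 or DSE4 (0.0561 to 0.0904). Of 12 protein genes of the mitochondrial genome 4 were lower and 1 higher in BS heart, and as many adjusted over the list alone (adjusted p = 0.0336, and adjusted p = 0.919 with an estimated correlation). COX2 averaged 57700 ± 2977 against 87370 ± 7765 TPM, and ATP6 went the other way at 24720 ± 3929 against 18590 ± 2871 TPM. The heart call was lost with median-ratio scaling (0.115) and without BS4 or DSE1 (0.0537 to 0.145). In liver 5 of the 12 were lower in BS, and 5 adjusted over the list alone (adjusted p = 0.0324, and adjusted p = 0.919 with an estimated correlation), with COX2 at 13360 ± 1383 against 21000 ± 652 TPM, a call lost without BS3 or DSE4 (0.0671 to 0.0735). In all, 20 of 149 camera tests passed, and fry, which asks whether the genes of a list move one way, passed 6 of these 20, namely MHC class I over tissues and in liver and lung, MHC class II over tissues, and the erythroid and heat shock lists in lung.

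For some genes the difference between the pig groups varied with the organ. SLC51B, measured in all 5 tissues, differed by log2 2.61 in liver and by log2 -1.25 in lung, with an interaction adjusted p = 1.76e-06 in limma. SNAP91 (log2 -2.33 in heart, interaction adjusted p = 6.66e-09), APOB (log2 -3.01 in kidney, 3.32e-09) and PGLYRP1 (log2 3.11 in spleen, 0.000132) passed as well. These 3 genes averaged under 1 TPM in both groups in 3, 3 and 2 of the tissues, where log2(TPM + 1) holds a difference near 0. Their interaction therefore partly reflects where the gene was expressed. CETN3 (interaction adjusted p = 0.877) and TMEM238 (0.414) did not pass the interaction test. In all, 1420 of 16905 genes passed it, and 569 with a pseudocount of 0.1. Without the animal DSE1 914 genes passed, without DSE2 879, without DSE3 686 and without DSE4 762.

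Transcript choice differed between the pig groups at fewer genes than between organs. PBX2, a homeobox cofactor (ENSSSCG00000001438, chromosome 7, 24221571 to 24226597, also covered by a joint identifier), used ENSSSCT00000001590 for 76.9 ± 5.28% of its TPM in BS and 6.67 ± 4.55% in DSE (SD, n = 4 each, limma adjusted p = 7e-06). ERAP1, which trims peptides for MHC class I and overlaps CAST, used the long-read transcript PB.3466.1 for 14.3 ± 9.62% in BS and 76.6 ± 6.81% in DSE. The gene's other tested transcript, PB.3466.2, also has 19 exons, with 4479 nt against 4496 nt for PB.3466.1. On this minus-strand gene both share the annotated 3' end and differ in the annotated start (103415197 against 103415214). Little sequence therefore tells these transcripts apart in short reads. PTGES3, a co-chaperone of HSP90, used PB.6824.2 for 22.9 ± 5.47% in BS and 83.7 ± 1.15% in DSE. In all, 432 of 4993 genes (8.65%) had a transcript that passed and shifted by at least 20 points of percent, and in 228 the leading transcript differed. Both comparisons called 117 genes, where independent calls would share 95.6. Genes with a mean of at least 20 TPM gave 130 calls, from fewer genes tested, and a shift of at least 40 points gave 26.

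Long reads gave the direction of some pig group differences from libraries made by another protocol. Of the 67 genes called over tissues that had enough full-length reads, 50 had the same direction in long reads, 74.6% (exact 95% interval 62.5 to 84.5, over genes, which are not independent), against 50.1% of genes that were not called. The share was 80.0% of 60 genes in heart, 75.6% of 90 in liver, 68.0% of 75 in spleen, 58.9% of 168 in kidney and 57.4% of 420 in lung, against 51.9, 51.1, 47.8, 42.2 and 51.6% of genes that were not called. In lung 76.1% of 71 genes higher in BS had the same direction, and 53.6% of 349 higher in DSE did (48.2 to 58.9, which includes 50). SLC51B had 34 full-length reads in BS and 13 in DSE over all tissues, out of 1255766 and 845215. Most pig group genes named by the rule, including CCDC152, CETN3 and TMEM238, had 0 full-length reads assigned in both groups. Long reads therefore gave no direction for them. The cardiac myosin MYH6 had 467 reads in BS heart and 7 in DSE heart, and its TPM in heart were higher in BS by log2 1.64 (limma adjusted p = 0.0435), a gene picked here after its values were seen.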

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

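The test of gene density in long reads, the count of genes with few full-length reads and the counts of other splits for gene levels were chosen after the results were seen.

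In short-read libraries BS exceeded DSE in 3 or more tissues at 140 genes, which had shorter transcripts (median 1447 nt against 2916 nt for genes tested in all tissues) and more neighbours (median 37 against 21 annotated genes within 500 kb). After subtracting the length trend 48.6% of them stayed at least 2-fold higher in every tissue that had called them, and 41.4% did after subtracting the gene density trend. Both shares lie between the bounds set in advance (under 20% or at least 70%), so neither trend can be excluded or shown as the whole cause. Of the 43 genes with at least 5 full-length reads, 34 were also higher in BS in the long-read libraries, made by another protocol, 79.07% (exact 95% interval 63.96 to 89.96, against 59.2% of other genes), which argues against an origin in short-read library preparation for these. For the other 97 genes full-length reads were too few to tell library preparation from a difference between the pigs, which stays open and untested.

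The wider relation of the BS minus DSE difference to gene density had Spearman rho 0.514 in short reads across 4876 genes with at least 20 full-length reads, and -0.0504 in long reads across the same genes. The long-read difference hardly followed the short-read difference at all across these genes (rho 0.0392), so the missing relation does not decide whether short-read library preparation was the cause, and this cannot be told apart from a difference between the pigs. The long-read difference went with transcript length instead (rho 0.482, against -0.38 in short reads), and each long-read value rests on 1 library per group and tissue, so a bias of the long reads that hides the relation stays open. GC content was not examined here. A biological difference between the pig groups stays open and was not tested.

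In 110 groups of 4 libraries 8 single values stood far from the rest of their group, where chance, which marks about 1 in 20 groups, gives 5.5. The share of TPM on ribosomal RNA genes was 2.09% in DSE4 heart, against 0.1405 to 0.2003% in the other DSE hearts. Long-read transcripts took 37.0% of TPM in DSE4 kidney, against 38.6 to 38.9%. ADGRG7 in kidney was 3.17 TPM in BS3, against 0.0988 to 0.290 in the other BS animals, and 16.9 TPM in DSE1, against 4.86 to 6.69. AGR2 in lung was 3.72 TPM in BS1, against 0.545 to 0.979, and 303 TPM in DSE2, against 9.15 to 32.5. PG-2 in spleen was 4.52 TPM in DSE3, against 1.46 to 1.68. NCBP2AS2 in spleen was 5.26 TPM in DSE1 and listed at 0 in the other DSE animals.

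The difference between BS and DSE varied with the tissue for 12 of the genes named within tissues, by the interaction test of limma. They had been picked for a large fold in 1 tissue, and 7 of them (SNAP91, APOB, ADGRG7, AGR2, PG-2, LTF and PGLYRP1) averaged under 1 TPM in both groups in 1 to 3 of the tissues, where log2(TPM + 1) holds a difference near 0. In heart SNAP91 had an adjusted p = 6.66e-09. In kidney APOB had 3.32e-09, CCDC152 0.00198 and ADGRG7 9.85e-05. In liver SLC51B had 1.76e-06, NPR2 9.23e-06 and SLC17A9 0.00307. In lung AGR2 had 0.00174 and HSPA6 0.0338. In spleen PG-2 had 0.00637, LTF 0.0374 and PGLYRP1 0.000132. Long reads at loci with no annotated transcript, outside every comparison, made up 9.10% of full-length reads.

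Other divisions of the same animals were refitted for the counts below and were not run for the gene lists, the long-read genes or the enriched transcripts. For the pig groups 1 of 35 splits, the real one, reached the real count in every comparison, the smallest share that 4 against 4 animals allow. Every other split mixes BS and DSE animals, which puts a difference between the pig groups into the spread and lowers the count. These splits therefore cannot exclude chance by themselves. The real and highest other counts were 318 and 1 in heart, 619 and 3 in kidney, 409 and 2 in liver, 1360 and 2 in lung, 414 and 3 in spleen, 234 and 1 over tissues, 1420 and 70 for the interaction and 432 and 1 for transcript usage. Between tissues 1 of 100 splits did so, with 1105 against 4 genes for transcript usage and, for gene levels, 288, 422, 362, 435 and 244 enriched genes and 120, 12, 123, 2 and 24 depleted genes in heart, kidney, liver, lung and spleen against a highest other count of 0. Groups that mix organs can hardly lie 4-fold from every other mixed group or shift usage by 20 points, so the splits between tissues decide little about chance.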

How the results depend on the processing

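The rescaling without mitochondrial and ribosomal RNA genes and the subtraction of length and density trends were chosen after the data were seen. Of the results that answer a comparison 242 values stayed within 1.5 times or their other bounds and 55 moved past them. These bounds are on the size of a count and not on its direction. With median-ratio scaling the share of pig group genes higher in BS went from 29.7 to 70.8% in lung and from 47.6 to 71.7% in spleen. Among single genes and lists, 660 values for tissue genes, 390 for pig group genes, 99 for transcripts and 185 for lists kept their direction and side of the threshold, and 75 values for lists kept their direction and lost the threshold. Some abundant genes had 0 full-length reads assigned, and the short-read depth is unknown. The long-read fit without each pig group in turn was not run, since dropping a whole group leaves no residual degrees of freedom. Where no cause is given, the cause was not tested.

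With a pseudocount of 0.1, which widens differences at low TPM by construction, depleted genes numbered 342 in heart, 29 in kidney, 487 in liver, 7 in lung and 72 in spleen, and enriched genes 735 in lung and 430 in spleen. Pig group genes numbered 614 in heart, 990 in kidney, 772 in liver, 633 in spleen and 691 over tissues. The interaction gave 569. No filter on low values gave 266 pig group genes in spleen, with more genes tested. Median-ratio scaling gave 501 enriched genes in heart, 554 in liver and 224 in lung, and 61 depleted genes in heart, 24 in kidney, 25 in liver and 7 in lung. With trends subtracted 209 pig group genes passed in heart, 404 in kidney, 268 in liver, 715 in lung and 266 in spleen. A 2-fold rule gave 562 enriched genes in heart, 1033 in kidney, 589 in liver, 1259 in lung and 821 in spleen. No minimum fold gave 4496 pig group genes in heart, 4650 in kidney, 3267 in liver, 6155 in lung, 3785 in spleen and 9342 over tissues. Camera with an estimated correlation called 0 lists and fry 13, against 20. A gene mean of at least 20 TPM, with fewer genes tested, gave 250 genes by tissue and 130 by pig group for transcript usage, and a shift of at least 40 points gave 303 and 26. DESeq2 called 52 long-read genes in kidney, 108 in liver and 15 in lung, and edgeR without the pig group term 22 in lung and 13 in spleen. At 20 or more full-length reads 99.5% of genes had the same tissue highest.

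Leaving out 1 animal at a time gave 447 to 1059 pig group genes in kidney, 870 to 2035 in lung and 686 to 1889 for the interaction. Counts moved past 1.5 times without BS3 in kidney (1059), without BS2 in lung (870) and without DSE1 (914), DSE2 (879), DSE3 (686) or DSE4 (762) for the interaction. In number of genes the lung count moved most without BS4, to 2035.

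With the animal as a block the tissue counts were 288, 422, 362, 436 and 245 enriched genes and 1115 genes for transcript usage. Between pig groups the samples share only a number. The number as a block gave 326 genes in heart, 581 in kidney, 397 in liver, 1183 in lung, 401 in spleen and 238 over tissues, 430 for transcript usage and 26 lists. With the animal as a block the interaction gave 1743. Animals of the same number correlated by -0.177 to 0.00779, and 0 of the BS animals correlated best with the DSE animal of their number. The block moved no count past 1.5 times.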

Other observations

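The check of abundant tissue genes in other tissues and the genes described first were chosen after their values were seen.

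Of 18 measured interferon response genes 16 had their highest mean in lung and 2 in spleen, and of 16 cell cycle genes 14 had it in spleen and 2 in lung. Of 10 erythroid genes 7 had it in spleen, 2 in kidney and 1 in heart, and all 10 endothelial genes had it in lung. No enrichment test of these lists passed, the lowest adjusted p being 0.207 for endothelium in lung (Fisher exact). The interferon-induced genes IFIT1 and OAS1 averaged 99.7 ± 27.9 and 99.7 ± 75.0 TPM in lung (SD, n = 8), against 9.53 ± 1.81 and 6.77 ± 0.853 TPM in kidney. TOP2A, a topoisomerase of dividing cells, averaged 20.8 ± 7.86 TPM in spleen and 13.2 ± 4.91 TPM in lung, against 0.451 ± 0.315 TPM in heart. HBB, a beta globin, averaged 10150 ± 11290 TPM in spleen, 3756 ± 4039 TPM in lung and 360 ± 313 TPM in kidney. The endothelial genes PECAM1 and CLDN5 averaged 454 ± 78.5 and 216 ± 93.7 TPM in lung, against 33.0 ± 4.04 and 8.58 ± 2.94 TPM in liver.

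The liver library of BS4 held heart muscle transcripts. MYL2 was at 47.1 TPM, TNNT2 at 65.4, MYL3 at 33.1 and MYH7 at 30.8, which are 0.418 to 0.633% of their heart means, and the next highest library outside the heart held 0.841, 1.37, 1.07 and 2.21 TPM. Albumin reached 39.2 TPM in the DSE3 heart library, 0.0679% of its liver mean.

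Some abundant genes had no full-length reads assigned. Reads were assigned only through long-read transcripts of the annotation, so 0 assigned reads do not show that none were sequenced. MYL2 at 11260 TPM, MYL3 at 5232 TPM, APOA2 at 645 TPM and AQP2 at 296 TPM had 0 full-length reads assigned in all 10 libraries, while MYH7 at 5480 TPM had 88 reads in BS heart and 48 in DSE heart. Full-length read counts ranked genes alike in BS and DSE, with Spearman rho 0.848 to 0.878 across 7929 genes in each tissue, and genes are not independent replicates.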
